A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

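Strand-specific total RNA sequencing was deposited for Saccharomyces cerevisiae BY4741 and for strains labelled as deleted for ECM32, SLH1, SKI2, DBP1 or DHH1, genes of RNA helicases. Per the labels, cells were grown to mid-log phase in YPD at 30°C, RNA was depleted of ribosomal RNA, and each of the 6 strains has 2 biological replicates, 12 libraries in all. The submitters' processing notes name Trim Galore, HISAT2 2.2.0, featureCounts 2.0.0, DESeq2 and genome build R64, without a role or order.

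The deposited table holds signal values, normalized densities, for 10891 features: 5897 protein-coding genes, 678 other open reading frames, 1664 XUTs (Xrn1-sensitive unstable transcripts), 1526 NUTs, 925 CUTs, 76 snoRNAs, 28 mitochondrial features, 4 features of the 2-micron plasmid, 1 other noncoding RNA and 92 ERCC spike-ins. A step of 1 read per column was taken from genes of annotated length. The length of each feature was then searched for, as the shortest that made all its values whole multiples of the steps. Such a length was found for every feature with reads, so that whole reads came back for 100% of the 124137 values above 0. The 100% thus rests partly on that search. Where the few reads of a feature share a common factor, its length and reads may be understated. The steps match size factors taken as median ratios over the 76 snoRNAs, with differences of up to 0.629%, against up to 20.5% for factors from 5610 protein-coding genes and up to 99.9% for factors from 60 ERCC spike-ins. The deposited values are therefore reads per nucleotide divided by a snoRNA size factor. By gene name, 5996 features matched the reference RefSeq R64 gene table. The counted length equals the annotated length for 851 features and is that long or longer for 5942. Depth per sample was 8.79 to 17.66 M reads, median 14.48 M. Replicates of a strain differed by 6.15 to 10.6 times the variance that counting alone gives (chi-square per degree of freedom), so replicate variation exceeds counting error. Of 16 genes lying almost wholly inside a gene on the other strand, 10 had less than 10% of the density of the outer gene (median ratio 0.0253). Counting by strand would give this, but so would leaving out reads that overlap more than 1 gene. The check therefore cannot tell whether reads were counted by strand.

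The design had set out a count-based test for counts and limma-trend for densities. The table holds densities, so limma-trend (limma 3.58.1, R 4.3.3) was run on log2 of density plus 0.005076, the 10th percentile of the values above 0. Features with a mean density above that value were tested, 9497 without the spike-ins, with all 12 libraries in a single model (6 residual degrees of freedom, prior 5.75). P-values were adjusted by the method of Benjamini and Hochberg within each comparison, with 0.05 as the threshold. Each deletion was compared with WT, and each deletion with every other. Folds and standard errors come from this model. For features with few reads, ratios of reads with 95% counting intervals are given. Where a group had 0 reads, 3 reads stand in for its upper limit, and the fold is given as "at least". The reads of the other group are taken as exact there, so the fold may overstate the limit where that group had few reads. The 95% intervals cover counting error only. With 2 libraries against 2, the smallest possible two-sided permutation p is 0.333, so p-values rest on the model.

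Gene lists and transcript classes were tested with camera (preset correlation 0.01), again with an estimated correlation and against protein-coding genes alone, and with fry. The preset correlation was the main test and called 88 tests. Adjusted p printed for lists and classes come from the estimated correlation unless named, which called 2. Results of fry are not given. The 34 lists and classes gave 170 tests over 5 comparisons, adjusted together. The lists, fixed before the data were examined, were ribosomal proteins, ribosome biogenesis, translation factors, decapping and deadenylation, exosome with Ski and nonsense-mediated decay factors, ribosome quality control, RNA helicases, environmental stress response, Hsf1 chaperones, gluconeogenesis with fatty acid oxidation, nuclear-encoded respiratory chain, mitochondrially encoded proteins, glycolysis, hexose transporters, phosphate regulon, iron regulon, sulfur amino acids, Gcn4 targets, seripauperins, cell wall, mating, MATa genes, MATalpha genes, meiosis, histones and the 5 deleted helicase genes. Members were listed from general knowledge of yeast genes. Auxotrophic marker genes had fewer than 3 members past the filter and were not tested. The comparisons, tests, lists and the rule for naming genes were set before the data were examined.

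The rule names the deleted gene and the other 4 helicases, up to 10 higher and 10 lower protein-coding genes and up to 5 higher and 5 lower XUTs with the largest changes past the threshold and both mutant libraries on the same side of both WT libraries, up to 4 members of each list called by camera with the preset correlation, and the neighbours of the deleted gene. Where no feature passed, the 3 with the smallest p are named as not past. Near-identical genes were looked for with BLAST 2.17.0 (95% identity over 50% of the length). Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

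Alternatives set beforehand were a pseudocount 4 times smaller or larger, no filter and a stricter filter (0.01336, the 25th percentile), size factors from protein-coding genes or snoRNAs, quantile normalization, robust variance shrinkage, a contrast against the mean of the other 5 strains, a replicate block, the 4 libraries of a comparison alone, and each replicate left out in turn. Added after seeing the data were voom on the recovered reads, spike-in factors with and without the first WT library, a fit without the libraries labelled ski2-delta and dbp1-delta, protein-coding factors for the contrasts and overlaps between deletions, and overlaps with 1 WT library for each deletion of a pair. XUT coordinates were not used here, so a split of XUTs by antisense overlap was not run. Sensitivity was tested on simulated data made from the recovered reads, with 100 features raised or lowered at each of 1.5-fold and 2-fold per comparison, and shared controls were simulated 20 times with unchanged strains.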

Results

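The series asks how XUTs, the long noncoding RNAs degraded by the cytoplasmic exonuclease Xrn1, respond to loss of each of 5 RNA helicases, Ecm32, Slh1, Ski2, Dbp1 and Dhh1. The labels give 2 biological replicates per strain. XUTs held 0.281 to 0.299% of endogenous reads in WT, and the 1664 XUTs of the table, of which 1419 were tested, had a median of 8.58 reads per library.

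The deleted genes were looked at first. In ecm32-delta, ECM32 (YER176W, chromosome V, 541690 to 545055 in build R64), a helicase with a part in translation termination, had 5 reads against 1336 in WT (log2 fold change -5.11, standard error 0.15, a value set by the pseudocount, which ran from -3.34 to -8.10 over the alternatives). In slh1-delta, SLH1 (YGR271W, chromosome VII, 1031791 to 1037694), a helicase of ribosome quality control, had 1 read against 2537, a ratio of WT to deletion of 3791 (95% counting interval 680 to 149800). In dhh1-delta, DHH1 (YDL160C, chromosome IV, 170410 to 171930), a helicase of decapping and translational repression, had 150 reads against 5008 (-5.25, standard error 0.12). The other 2 strains went against their labels. SKI2 (YLR398C, chromosome XII, 915156 to 919019), the helicase of the Ski complex, stood at 146% of WT in the libraries labelled ski2-delta and at 0.110% in the libraries labelled dbp1-delta, where it had 3 reads against 3036 in WT (ratio 890, interval 304 to 4320). DBP1 (YPL119C, chromosome XVI, 324411 to 326264), a helicase of translation initiation related to Ded1, stood at 3.68% of WT in the libraries labelled ski2-delta, 6 reads against 226, and at 150% in the libraries labelled dbp1-delta. Both replicates of each strain did so. The labels are kept as names below, so any direction given for these 2 strains belongs to the libraries so labelled and not to the gene in the name.

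**Figure D1:**
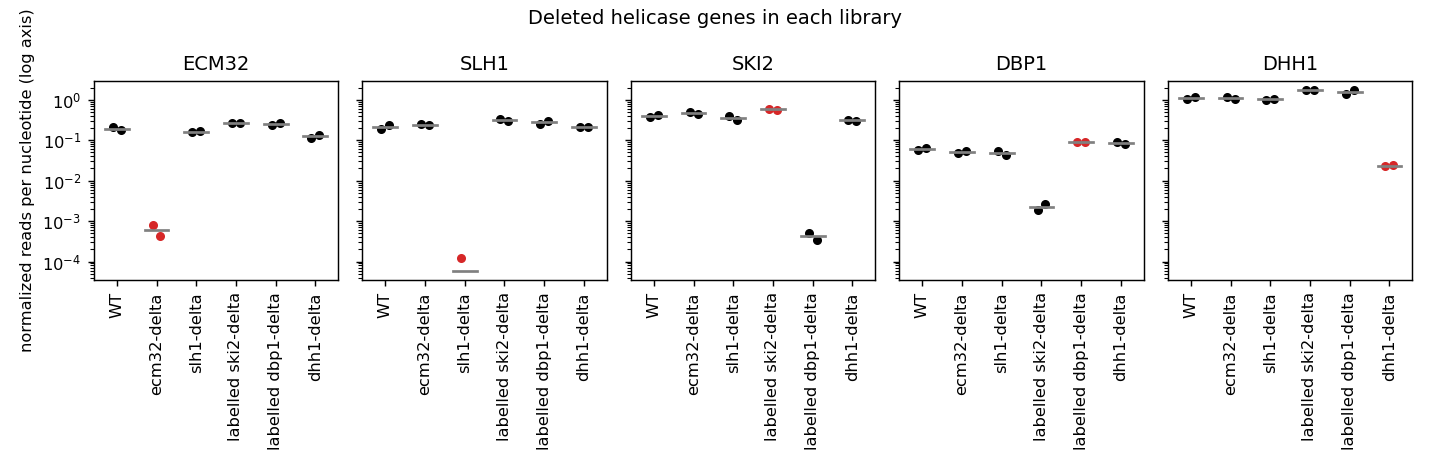
Density (normalized reads per nucleotide, log axis) of the 5 helicase genes in each library, with the mean of each strain as a line and the libraries labelled as deleted for that gene in red. The second slh1-delta library had 0 SLH1 reads and has no point on the log axis.

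The choice of scaling sets the zero of every comparison. As deposited, the median log2 fold change of all 9497 features was 0.08 in ecm32-delta, -0.09 in slh1-delta, 0.39 and 0.33 in the libraries labelled ski2-delta and dbp1-delta, and -0.20 in dhh1-delta. With factors from protein-coding genes these medians were -0.02, 0.00, -0.01, 0.01 and -0.16. With spike-in factors they were -0.16, -0.43, -0.33, -0.19 and -0.40, and without the first WT library 0.33, 0.07, 0.18, 0.32 and 0.09. In that WT library spike-ins took 1.22% of reads, against 1.72 to 2.69% in the other 11. Medians of the gene lists are therefore given relative to the median of all features, or named as unadjusted for it.

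**Figure D2:**
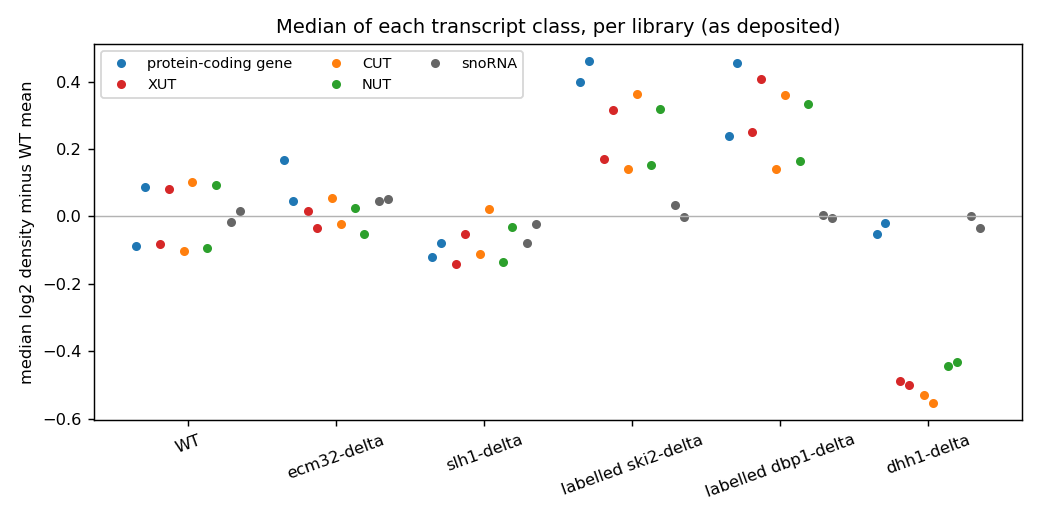
Median log2 density of each transcript class in each library minus the WT mean, as deposited. Points are single libraries.

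In ecm32-delta, FBP1 (YLR377C, chromosome XII, 873746 to 874792), the gluconeogenic fructose-1,6-bisphosphatase, rose by 2.36 on the log2 scale (standard error 0.30, adjusted p = 0.0173, n = 2 against 2), with 162 reads against 18. TPO2 (YGR138C, chromosome VII, 763762 to 765606), a polyamine exporter 97.2% identical to TPO3 over 76.4% of its length, rose by 1.29 (standard error 0.18, adjusted p = 0.0189). XUT0921 rose by 1.75 (standard error 0.24; 23 against 4 reads). XUT1162 had 0 reads against 49, at least 19.5-fold lower, and XUT1427 had 0 against 7, at least 2.78-fold lower. ECM32 and CUT571 also fell, the latter named after its values were seen (density 0 in both deletion libraries, 0.0279 and 0.0264 in WT). With these, limma-trend called 3 features higher and 4 lower out of 9497, with 825 at unadjusted p under 0.05 and 9 called by voom. All 3 higher features were also called higher in the libraries labelled ski2-delta, 2 in those labelled dbp1-delta and 2 in dhh1-delta. These comparisons share their WT libraries, so the 3 rises are not particular to ecm32-delta and could rest on low WT values, which was not tested. The other helicase genes and the neighbours of ECM32 did not pass (TMT1 -0.08, YER175W-A 0.20, BMH1 0.16, PDA1 0.02). Higher calls made up 42.9% as deposited, 31.2% with protein-coding factors (5 higher, 11 lower), and 83.3% with spike-in factors and no first WT library (10 higher, 2 lower). Without the first WT library 2 features were called, ECM32 and a XUT other than these, and without any of the other 3 libraries 1, ECM32. FBP1, TPO2 and the 3 XUTs each passed in 0 of these 4 fits.

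Among gene groups of ecm32-delta, no list had more than 1 member called over all features: FBP1 in gluconeogenesis and ECM32 in the RNA helicases. Ribosome biogenesis genes had a median of 0.25 above that of all features, and the nuclear-encoded respiratory chain 0.22 above it, both with adjusted p = 0.658 with an estimated correlation. Adjusted over the list alone, 9 of 35 respiratory chain genes rose and none fell, and 11 of 41 RNA helicases rose and 1 fell (adjusted p = 0.691 with an estimated correlation). Mating genes stood 0.27 lower than all features (median relative to all -0.27), with 0 of 17 called over all features and 1 lower adjusted over the list alone (adjusted p = 0.658 with an estimated correlation).

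In slh1-delta, SLH1 was the only feature that passed, with 0 higher and 1 lower by limma-trend, 668 at unadjusted p under 0.05 and 20 called by voom. Higher calls were 0% as deposited, 50% with protein-coding factors (2 higher, 2 lower) and 57.1% after quantile normalization (4 higher, 3 lower). Without the first WT library 2 features were called, 1 of them a XUT. The XUTs with the smallest p were not past: XUT0271 at -1.22 (adjusted p = 0.166), XUT0747 at 2.35 (0.205) and XUT0391 at 1.42 (0.349; 17 against 3 reads, ratio 3.79, interval 1.10 to 20.2). The neighbours HUA1 (0.48), YTA7 (-0.09) and EFG1 (-0.10) did not pass. Genes induced in the environmental stress response had a median 0.27 above that of all features, with adjusted p = 0.658 with an estimated correlation. Over all features 0 of its 44 members passed. Adjusted over the list alone 5 rose and 0 fell. Unadjusted for all features, the median of the list was 0.17 as deposited and -0.16 with spike-in factors. Ribosome biogenesis genes had a median of -0.15 relative to all features, with 0 of 73 called over all features, and 0 higher and 2 lower adjusted over the list alone (adjusted p = 0.691 with an estimated correlation).

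In the libraries labelled ski2-delta, where DBP1 and not SKI2 was nearly absent, protein-coding genes with large increases were FBP1 (2.21, standard error 0.30), TPO2 (1.60, 0.18), HSP12 (1.58, 0.20), a small stress protein of membranes (YFL014W, chromosome VI, 107256 to 107585), SRL1 (1.47, 0.20), a cell wall mannoprotein (YOR247W, chromosome XV, 797676 to 798308), and, from the cell wall list, CWP2 (1.27, 0.17), a major cell wall mannoprotein (YKL096W-A, chromosome XI, 259253 to 259531). SDH4, a membrane subunit of succinate dehydrogenase (YDR178W, chromosome IV, 817950 to 818495), rose by 0.96 (0.12). These 6 genes passed with protein-coding factors too, at 1.86, 1.19, 1.19, 1.04, 0.84 and 0.53. Against the mean of the other 5 strains HSP12 turned (-0.015) and the others did not. That mean holds dhh1-delta and the libraries labelled dbp1-delta, where HSP12 rose more, so the turn does not go against its rise over WT. The other 6 of the 10 coding genes with the largest increases were short reading frames, at 1.47 to 1.76, among them YDR169C-A (1.76; 12 against 4 reads) and YLR285C-A (1.53; 732 against 324 reads), and none of these 6 passed with protein-coding factors. After DBP1, with 6 reads against 226, and YFR012W-A, with 0 reads against 6, the largest decrease of a coding gene was in IRC13 (-2.46, 0.20, and -2.89 with protein-coding factors). IRC13 is a dubious reading frame (YOR235W, chromosome XV, 779870 to 780184) that overlaps the U3 snoRNA gene SNR17A by 78 of 315 nt. YFR012W-A was at least 1.42-fold lower only if its 6 WT reads are taken as exact. MIN10, which encodes a small mitochondrial protein (YFR032C-B, chromosome VI, 223710 to 223973), fell by 0.91 (0.11).

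Of the 9497 features, 3732 were called higher and 70 lower as deposited, of which 160 and 35 by 2-fold or more, and 4023 called by voom. Higher calls made up 98.2%, but 34.2% with protein-coding factors (27 higher, 52 lower), 40% after quantile normalization (32 and 48) and 16 higher against 99 lower with spike-in factors. Leaving out a library gave 63 calls without the first WT library, 3749 without the second, 2112 without the first labelled library and 48 without the second. Protein-coding genes gave 3380 higher and 9 lower, and the neighbours of SKI2, VPS33 (0.49), AFG2 (0.55), BDF1 (0.45) and DUS3 (0.42), were among them, none of them with protein-coding factors. As SKI2 kept its reads in these libraries, its neighbours cannot show an effect of a deletion. Neighbours of DBP1, the gene lacking reads here, are not given. The helicase genes ECM32 (0.47), SLH1 (0.54), SKI2 (0.54) and DHH1 (0.66) likewise rose as deposited only, and had values below 0 with spike-in factors.

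Against this shift, the nuclear-encoded respiratory chain stood 0.20 above the median of all features, with 34 of 35 genes higher and 0 lower as deposited, 35 adjusted over the list alone, and 3 higher with protein-coding factors (adjusted p = 0.658 with an estimated correlation). Of 23 mitochondrial features 15 rose and 1 fell as deposited (median 0.40 above all features; adjusted p = 0.908 with an estimated correlation), and with protein-coding factors 0 rose and 1 fell. Ribosome biogenesis genes rose in 60 of 73 cases as deposited and in 0 with protein-coding factors (relative median 0.11), and RNA helicases in 32 with 1 lower, against 0 and 1 (adjusted p = 0.709 for both with an estimated correlation). Stress response genes gave 24 higher and 0 lower of 44, 2 of them with protein-coding factors, Hsf1 chaperones 16 and 0 of 22, 0 of them with protein-coding factors, and Gcn4 targets 37 and 0 of 48, 0 of them with protein-coding factors (adjusted p = 0.746, 0.709 and 0.740 with an estimated correlation). Unadjusted for all features, the medians of these 5 lists and of the respiratory chain were below 0 with spike-in factors, and above 0 with those factors and no first WT library. The snoRNAs, to which the deposited values are scaled, stood lower than all features (2 higher, 5 lower, median relative to all features -0.39, adjusted p = 0.00167 with an estimated correlation). Scaling holds their own median near 0 (-0.0011), so this restates the rise of the other features and is no separate result.

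In the libraries labelled dbp1-delta, where SKI2 and not DBP1 was nearly absent, HSP12 rose by 1.88 (standard error 0.20), TPO2 by 1.74 (0.18), YGP1, a secreted glycoprotein of starved cells (YNL160W, chromosome XIV, 336545 to 337609), by 1.68 (0.13), and YRO2, a plasma membrane protein (YBR054W, chromosome II, 343101 to 344135), by 1.59 (0.17). With protein-coding factors these rose by 1.57, 1.41, 1.33 and 1.25. IRC13 fell by 2.28 (0.20). PHO89, the sodium-phosphate symporter (YBR296C, chromosome II, 796798 to 798522), fell by 1.27 (0.17), and by 1.61 with protein-coding factors. PHO12, an acid phosphatase 99.7% identical to PHO11, fell by 0.90 (0.15), though without 1 library its adjusted p reached 0.0567. FRE7 (2.32, 0.62) and FRE1 (1.62), both metalloreductases, rose as well but passed in 0 of the 4 fits without 1 library. XUT0893 rose by 2.38 (0.24; 210 against 43 reads) and XUT0921 by 1.90 (0.24).

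Of all features, 1634 rose and 39 fell as deposited, of which 129 and 21 by 2-fold or more, and voom called 2319. Higher calls made up 97.7%, but 41.2% with protein-coding factors (28 higher, 40 lower), 44.4% after quantile normalization (32 and 40), and 31 against 35 with spike-in factors. Leaving out a library gave 36 calls without the first WT library, 2449 without the second, 3077 without the first labelled library and 20 without the second. The neighbours of DBP1, VPS30 (0.26), YPL119C-A (0.67) and IDI1 (0.21), did not pass, and MRP51 (0.39) did, as deposited only. As DBP1 kept its reads in these libraries, its neighbours cannot show an effect of a deletion. Neighbours of SKI2, the gene lacking reads here, are not given. Of the helicase genes DHH1 rose as deposited only (0.49), and DBP1 (0.55, adjusted p = 0.0511), ECM32 (0.35) and SLH1 (0.35) did not pass.

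Chaperone genes under Hsf1 stood 0.22 above the median of all features in these libraries, with 19 of 22 higher and 0 lower, 21 adjusted over the list alone and 1 with protein-coding factors (adjusted p = 0.658 with an estimated correlation). HSP42, a small chaperone, rose by 1.26 (0.92 with protein-coding factors), with an adjusted p of up to 0.0522 when 1 library was left out. Stress response genes stood 0.31 above all features, with 25 of 44 higher and 0 lower, 37 adjusted over the list alone and 4 with protein-coding factors (adjusted p = 0.658 with an estimated correlation). The phosphate regulon stood lower (median relative to all -0.33): PHO89, PHO12 and PHO11 fell, the last passing in 1 of 4 fits without 1 library, 0 of 16 rose, and 7 fell with protein-coding factors (adjusted p = 0.658 with an estimated correlation). Mating genes stood lower still (-0.42 relative to all; 0 higher and 0 lower as deposited, 1 lower with protein-coding factors; adjusted p = 0.605 with an estimated correlation). Of the mating-type genes, YCR041W, whose sequence also stands at HMLALPHA1, rose by 1.74 (0.23; 1.42 with protein-coding factors), and MATALPHA1, identical to HMLALPHA1, had 14 reads against 2 (ratio of deletion to WT 7.96, interval 1.83 to 72.1) and passed in 2 of 4 fits without 1 library. The respiratory chain gave 26 higher and 0 lower of 35, 0 of them with protein-coding factors (adjusted p = 0.691 with an estimated correlation). The snoRNAs again stood lower than all features (2 higher, 3 lower, -0.32 relative to all, adjusted p = 0.00167 with an estimated correlation). With their own median held near 0 by the scaling (0.0042), this too restates the rise of the other features.

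In dhh1-delta, the largest increase of a coding gene was in TMA10 (YLR327C, chromosome XII, 783127 to 783387), a ribosome-associated protein, at 6.03 on the log2 scale (standard error 0.24), 65.2-fold, with 5407 against 58 reads. Next came YER053C-A (5.71, 0.32), the cell wall mannoprotein HPF1 (4.21, 0.22), HSP12 (4.19, 0.20, 18.3-fold), the hexokinase HXK1 (YFR053C, chromosome VI, 253592 to 255049; 3.82, 0.21), RGI1, a protein of respiratory growth (3.73, 0.19), the high-affinity hexose transporter HXT7, 99.8% identical to HXT6 (3.71, 0.17), RTC3 (3.64), the metalloreductase FRE7 (3.63, 0.62) and the glycogen phosphorylase GPH1 (3.50, 0.20). After DHH1 itself, the largest decreases of coding genes were in the metallothionein CUP1-2, identical to CUP1-1 (-5.07, 0.70), BSC1 (-4.54, 0.25), PRM7 (-4.30, 0.29), ANB1, the anaerobic form of eIF5A (-3.87, 0.27), and HXT1, a low-affinity glucose transporter (YHR094C, chromosome VIII, 290913 to 292625; -3.81, 0.15). TIR1, an anaerobic cell wall mannoprotein (-3.25, 0.19), the repressor MIG3 (-3.20, 0.23) and HXT3, also a low-affinity glucose transporter (YDR345C, chromosome IV, 1162957 to 1164660; -3.08, 0.18), fell too, and YOR293C-A had 0 reads against 9, at least 4.18-fold lower. Each of these genes kept its direction and its call under all 19 alternatives.

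**Figure D3:**
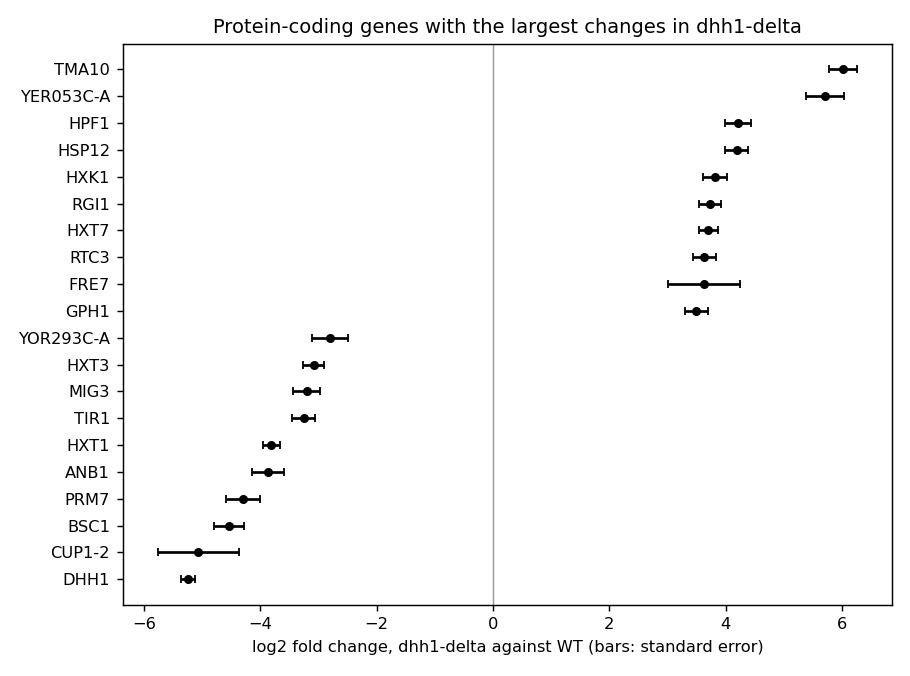
Log2 fold change and standard error in dhh1-delta of the 10 protein-coding genes with the largest increases and the 10 with the largest decreases. The fold of YOR293C-A, with 0 reads in dhh1-delta, is set by the pseudocount.

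Of all features in dhh1-delta, 1297 rose and 2307 fell, 394 and 748 by 2-fold or more, and voom called 4140. Higher calls made up 36.0%, against 18.2% with spike-in factors (287 and 1288) and 74.3% with those factors and no first WT library (1895 and 657). Leaving out a library gave 2206 to 3112 calls, the lowest without either dhh1-delta library. Of the other helicase genes, ECM32 fell by 0.59, passing in 2 of 4 fits without 1 library (adjusted p of up to 0.0892), while SKI2 (-0.35, adjusted p = 0.0508), DBP1 (0.47, 0.0526) and SLH1 (-0.03) did not pass. Of the neighbours of DHH1, ENT1 (0.28), MHF2 (0.44) and STE7 (-0.07) did not pass, and YDL159W-A had 15 reads against 0, at least 3.59-fold higher.

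Genes of the nuclear-encoded respiratory chain rose together in dhh1-delta: 35 of 35, with a median 1.48 above that of all features, among them QCR10 (2.18) and RIP1 (1.94) of complex III, SDH4 (1.86) and COX7 of cytochrome oxidase (1.82). Camera called the list with the preset correlation and gave adjusted p = 0.605 with an estimated correlation. With spike-in factors 23 rose and 0 fell. Of the 44 stress response genes 31 rose and 4 fell (median 1.40 above that of all features; 31 and 5 adjusted over the list alone; adjusted p = 0.605 with an estimated correlation). Of the 22 cell wall genes 13 rose and 0 fell, with CWP1 (2.55), SED1 (2.53), HSP150 (2.27) and PST1 (2.22), all structural or secreted mannoproteins, in the lead (adjusted p = 0.658 with an estimated correlation). Of 10 histone genes 9 rose and 0 fell, among them HHT1 of H3 (1.03), HTB1 of H2B (0.95) and HHF1 of H4, 97.4% identical to HHF2 (0.90), but 0 did so with spike-in factors (adjusted p = 0.658 with an estimated correlation).

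Among mRNA decay genes of dhh1-delta, 11 of 29 decapping and deadenylation genes rose and 3 fell (adjusted p = 0.709 with an estimated correlation), and 1 rose and 1 fell with spike-in factors. EDC1 (3.21) and EDC2 (1.17), enhancers of decapping, rose, as did DCS1 (1.15), the scavenger decapping enzyme, and its paralog DCS2 (1.22). Of 17 mating genes 8 rose and 1 fell (adjusted p = 0.691 with an estimated correlation), with FIG1 (2.03), AGA1 (1.64), PRM1 (1.27) and FIG2 (1.06), and of 6 MATa genes 4 rose and 1 fell (adjusted p = 0.658 with an estimated correlation). AGA2, the a-agglutinin subunit (2.28), and the a-factor genes MFA1 (1.74) and MFA2 (1.58) rose, and STE6, the a-factor exporter, fell by 0.39, passing in 1 of 4 fits without 1 library. Of 41 RNA helicases 25 fell and 0 rose (adjusted p = 0.709 with an estimated correlation), among them MAK5 (-0.80), DBP2 (-0.76) and HCA4 (-0.75), although 3 fell and 0 rose with spike-in factors, and 2 rose and 3 fell without the first WT library as well. Of 73 ribosome biogenesis genes 31 fell, NSR1 (-0.95) and MPP10 (-0.89) among them, and 1 rose, TIF6 (1.38, standard error 0.13), a factor of the large subunit. That list gave adjusted p = 0.754 with an estimated correlation and 5 lower with spike-in factors.

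The remaining lists were not called in dhh1-delta. They split as follows, higher and lower: ribosomal proteins 6 and 22 of 137 (16 and 0 with spike-in factors and no first WT library), translation factors 2 and 16 (5 and 2 by that scaling), the exosome with Ski and decay factors 2 and 5 (4 and 1 by that scaling), ribosome quality control 0 and 1 (1 and 0 by that scaling), Hsf1 chaperones 5 and 9 (1 and 0 with spike-in factors), gluconeogenesis 4 and 1, mitochondrially encoded proteins 0 and 0, glycolysis 3 and 3 of 18, and hexose transporters 5 and 2 of 10. The phosphate regulon gave 7 and 5, the iron regulon 7 and 5, sulfur amino acids 5 and 6 (6 and 4 with spike-in factors and no first WT library), Gcn4 targets 7 and 12 (10 and 1 with the same), seripauperins 1 and 6 of 13, MATalpha genes 0 and 1, and meiosis 0 and 8 of 19. Of the 5 deleted helicase genes 0 rose and 2 fell, DHH1 and ECM32.

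XUTs fell more often than they rose in dhh1-delta. There 23 of 1419 XUTs rose and 430 fell, 18 and 250 by 2-fold or more. Their median was -0.50 unadjusted for all features and -0.30 relative to them, and they held 0.181 and 0.183% of endogenous reads. XUT0649 rose by 2.06 (standard error 0.22; 276 against 43 reads), while XUT1525 (-2.70, 0.18; 39 against 266 reads), XUT0270 (-2.86, 0.31) and XUT0275 (3 against 26 reads, ratio of WT to deletion 12.1, interval 3.70 to 62.3) fell. Higher calls made up 5.1% as deposited and 5.2% with protein-coding factors (27 higher, 490 lower), but 40% after quantile normalization (110 higher, 165 lower), where the unadjusted median was -0.04. With spike-in factors and no first WT library 43 rose and 182 fell, and without the second WT library 257 XUTs were called. The adjusted p for XUTs as a class was 0.691 with an estimated correlation. In ecm32-delta 1 XUT rose and 2 fell (92 at unadjusted p under 0.05; 1 called by voom), and in slh1-delta 0 rose and 0 fell by limma-trend (101 at unadjusted p under 0.05; 2 called by voom), with class medians of -0.08 and -0.01 relative to all features and adjusted p of 0.691 and 0.833 with an estimated correlation. In the libraries labelled ski2-delta 108 rose and 15 fell, and in those labelled dbp1-delta 99 rose and 9 fell, with medians relative to all features of -0.16 and -0.03 (adjusted p = 0.605 and 0.658 with an estimated correlation). With protein-coding factors 2 rose and 4 fell, and 4 rose and 1 fell. These counts were 8 each without the first WT library and 6 and 5 without the second labelled library. On simulated data with 200 XUTs raised 2-fold and no other feature changed, 0 to 7 were recovered one by one in each comparison, whereas the median of the raised XUTs came out at 0.79 to 0.84. Single XUTs changed 2-fold may thus be missed where few features pass, as in ecm32-delta and slh1-delta. The simulation does not describe dhh1-delta, where 453 XUTs passed among many other features. Of 100 features of any class changed 2-fold, 51 to 63 were recovered. Both simulations gave every feature the same dispersion, 0.006997, taken from features with many reads. They held no difference of scaling between replicates, whereas the real WT libraries differed by 0.16 in the median of XUTs. Recovery in the real data may therefore be lower.

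**Figure D4:**
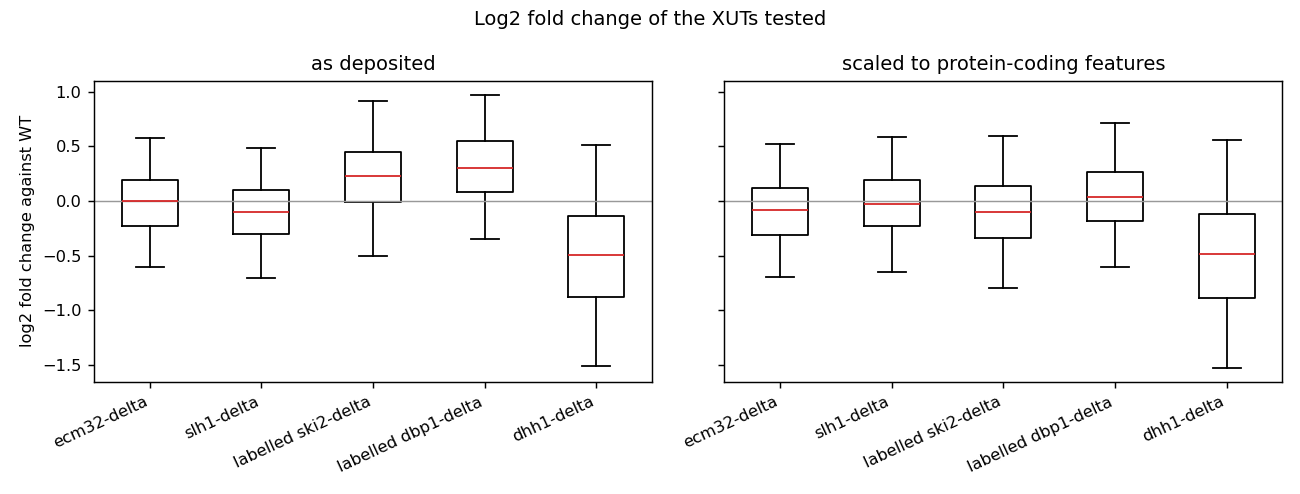
Log2 fold change against WT of the 1419 XUTs tested in each comparison, as deposited on the left and with protein-coding size factors on the right. Boxes are quartiles, whiskers reach from the 5th to the 95th percentile, and the strain names are the labels.

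Of the other unstable transcripts in dhh1-delta, 13 of 830 CUTs were higher and 263 lower (median -0.35 relative to all features, adjusted p = 0.709 with an estimated correlation), and 37 of 1103 NUTs higher and 296 lower (-0.25, adjusted p = 0.731 with an estimated correlation). After quantile normalization CUTs gave 49 and 122 and NUTs 111 and 108. Protein-coding genes gave 1176 higher and 1224 lower, against 218 and 371 with spike-in factors and 1694 and 228 with those factors and no first WT library. The snoRNAs gave 6 higher and 12 lower, against 0 and 6, and 17 and 2. In the libraries labelled ski2-delta 78 CUTs rose and 20 fell as deposited, against 1 and 19 with protein-coding factors, and 81 NUTs rose and 8 fell, against 1 and 6. In those labelled dbp1-delta 40 CUTs rose and 12 fell, against 2 and 10, and 54 NUTs rose and 3 fell, against 2 and 3. In ecm32-delta and slh1-delta at most 1 CUT or NUT was called by limma-trend as deposited.

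Deletions were compared with each other directly. XUTs called between dhh1-delta and another strain numbered 443 for ecm32-delta, of which 421 were higher in ecm32-delta, 309 for slh1-delta, 737 for the libraries labelled ski2-delta and 802 for those labelled dbp1-delta (431, 445, 438 and 561 with protein-coding factors). Between the libraries labelled ski2-delta and dbp1-delta 0 XUTs and 2 features were called by limma-trend, SKI2 and DBP1 themselves. With protein-coding factors 9 features were called, 3 of them XUTs. As deposited, the same 1327 features rose in both, where 642.1 would be shared by n1 x n2 / N, and 19 fell in both (0.3 by n1 x n2 / N), IRC13 and MIN10 among them. Simulated unchanged strains shared 0, but these give hardly any calls and hold no shift of scaling, so that count is no yardstick. Nor is n1 x n2 / N under either scaling, as it takes the comparisons as independent though they share their WT libraries. An excess over it therefore does not show a shared response. With protein-coding factors, tried after seeing the data, 9 rose in both (0.08 by n1 x n2 / N) and 21 fell in both (0.22), IRC13 and MIN10 again among them. As deposited, the correlation of their changes was 0.55, against 0.50 in simulation from the shared WT libraries alone, and the covariance exceeded the simulated value by 0.0344. With 1 WT library given to each of the 2 instead, also tried after seeing the data, the correlation was 0.16 either way round (covariance 0.0258 and 0.0255). Over the 10 pairs of deletions it ran from 0.0258 to 0.199, the highest being slh1-delta with dhh1-delta.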

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

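The tests of explanations in this part were all chosen after the results were seen.

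SKI2 and DBP1 went against the strain labels. If the labels of these strains had been exchanged, SKI2 should be nearly absent in the libraries labelled dbp1-delta and DBP1 in those labelled ski2-delta, and the higher of these levels was 3.68% of WT. If instead the names of SKI2 and DBP1 had been exchanged in the table, the entry named SKI2 should have the length of DBP1, but its counted length is 4001 nt, against annotated lengths of 3864 nt for SKI2 and 1854 nt for DBP1, which rules that out. An exchange of strains, cultures, libraries or labels may lie behind the pattern, and 3.68% cannot tell these apart.

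As deposited, the median of all features stood at 0.39 and 0.33 in the libraries labelled ski2-delta and dbp1-delta, with far more features called higher than lower. A loss confined to RNA of up to 200 nt would put longer snoRNAs with short mRNAs. Coding features of up to 500 nt stood above snoRNAs over 200 nt by 0.26 or more on the log2 scale (231 and 20 features). That gap argues against such a loss. The sets were not matched on length, so a loss that reaches longer RNA is not addressed. The scaling of the deposited values to the snoRNAs and a larger amount of RNA per spike-in both stay open, as spike-in factors, the reference outside the cells, gave medians over all features from -0.33 with all libraries to 0.32 without the first WT library. Protein-coding factors remove any general rise, whatever its cause, and do not decide between them.

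In dhh1-delta 430 of 1419 XUTs fell and 23 rose. Scaling to the snoRNAs alone does not account for it, since the XUT median closest to 0 under protein-coding and spike-in factors, unadjusted for all features, was -0.30, with spike-in factors and no first WT library. Relative to all features the closest was -0.29, with spike-in factors and all libraries. Quantile normalization, which gives every library the same distribution, took the unadjusted XUT median to -0.04 (110 higher, 165 lower). A fall of every feature of low density could be part of it: over 20 bins of matched density 1277 XUTs had a median of -0.48 and 442 coding features -0.31, a difference of -0.17 (interval from 1000 draws -0.28 to -0.07). Between replicate libraries this difference had an SD of 0.0465. Taken against the mean of the 12 libraries, XUTs minus matched coding features came to -0.13 and -0.20 in the dhh1-delta libraries. In the other libraries this ran from -0.02 to 0.11. The difference of -0.17 lies beyond 2 of these SD and its interval lies below 0, but the near end of the interval is within 2 SD. The test asked for the whole interval beyond 2 SD, so it cannot tell whether low density accounts for all of the fall.

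Deletions that differ from each other, by the number of features called between them, were ecm32-delta and slh1-delta (48 as deposited, 134 with protein-coding factors), ecm32-delta and the libraries labelled ski2-delta (1289 and 68), ecm32-delta and those labelled dbp1-delta (706 and 334), ecm32-delta and dhh1-delta (3800 and 4313). The list goes on with slh1-delta and the libraries labelled ski2-delta (4695 and 128), slh1-delta and those labelled dbp1-delta (4197 and 43), slh1-delta and dhh1-delta (2875 and 4070), and the libraries labelled ski2-delta and dbp1-delta (2 and 9). Between dhh1-delta and the libraries labelled ski2-delta 5598 and 4263 features were called, and between dhh1-delta and those labelled dbp1-delta 5378 and 4481.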

How the results depend on the processing

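Voom, spike-in factors, the fit without the libraries labelled ski2-delta and dbp1-delta, protein-coding factors between deletions, and 1 WT library for each deletion of a pair were chosen after seeing the data. Except where the alternative's own construction is named, the cause was not tested. Alternatives that split XUTs by antisense overlap, of 1 nt or of most of the XUT, were not run, as XUT coordinates were not used here. Factors from snoRNAs moved almost nothing, being those of the deposited values. The counts of called features stayed within 1.5-fold in 8, 9 and 16 of 19 alternatives in ecm32-delta, slh1-delta and dhh1-delta, and in 10 and 9 of 18 in the libraries labelled ski2-delta and dbp1-delta. In the same order, XUT counts did so in 10, 14, 13, 9 and 10, and XUT medians stayed within the replicate spread of 0.0882 in 16, 16, 11, 12 and 11. Of the values of named genes under alternatives, 3402 kept their call or lack of one, 852 lost the call, 37 gained one and 55 turned. A gene turned if its direction changed and it was called in either fit. Changes of direction with no call in either fit are among the 3402. Depth limits the XUTs, with a median of 8.58 reads over the 1664 of the table. XUT medians in this part are unadjusted for the median of all features, and relative to it some have the other sign. With the larger pseudocount they are then -0.19 and -0.10 in the libraries labelled ski2-delta and dbp1-delta and -0.12 in dhh1-delta, and with spike-in factors and all libraries -0.055, 0.043, -0.042, 0.054 and -0.29. Values run in the order ecm32-delta, slh1-delta, libraries labelled ski2-delta, libraries labelled dbp1-delta, dhh1-delta, unless named.

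With a pseudocount 4 times larger ecm32-delta had 2 features and 0 XUTs, and XUT medians were 0.14 and 0.18 in the libraries labelled ski2-delta and dbp1-delta and -0.26 in dhh1-delta, as a larger pseudocount pulls low densities together. With a pseudocount 4 times smaller the dhh1-delta median was -0.64. With robust shrinkage slh1-delta had 2 features, and with the stricter filter 3. With voom slh1-delta had 20 features and 2 XUTs, ecm32-delta 1 XUT, and the dhh1-delta XUT median was -0.71. Without the libraries labelled ski2-delta and dbp1-delta in the fit ecm32-delta had 11 features. With the 4 libraries of the comparison alone the counts were 20, 11, 7 and 452, with 0 XUTs in the libraries labelled ski2-delta. With a replicate block (paired by replicate number) features were 7, 1, 3900, 1607 and 3683 and XUTs 2, 0, 135, 109 and 470.

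Against the mean of the other 5 strains, a control that itself holds deletions, ecm32-delta had 222 features, slh1-delta 2066 and the libraries labelled dbp1-delta 2571. XUTs were 6, 27, 265, 310 and 725, and XUT medians 0.40 in the libraries labelled dbp1-delta and -0.59 in dhh1-delta. Genes that turned were TPO2 in ecm32-delta (-0.16), ECM32 (0.72), SKI2 (0.99) and DHH1 (0.72) in slh1-delta, HSP12 (-0.015), SOL4 (-0.19) and YGP1 (-0.037) in the libraries labelled ski2-delta, EDC1 (-0.013) and PST1 (-0.0089) in those labelled dbp1-delta, and ECM32 (0.32), SLH1 (0.85) and SKI2 (0.75) in dhh1-delta. For the helicase genes, strains lacking reads of the gene are part of that control. For HSP12, EDC1 and PST1 it holds dhh1-delta, where each of them rose over WT. For TPO2 it holds the libraries labelled ski2-delta and dbp1-delta, where TPO2 rose more than in ecm32-delta.

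With protein-coding factors the features were 16, 4, 79 and 68 in the first 4 comparisons, XUTs 6 and 5 and XUT medians -0.10 and 0.039 in the libraries labelled ski2-delta and dbp1-delta, and DUS3 turned in the former (-0.0074). Between deletions these factors gave 134 features for ecm32-delta and slh1-delta, 68 and 334 for ecm32-delta and the libraries labelled ski2-delta and dbp1-delta, 128 and 43 for slh1-delta and the same, and 9 between the latter. After quantile normalization slh1-delta had 7 features and the libraries labelled ski2-delta and dbp1-delta 80 and 72, with 4 and 5 XUTs and XUT medians of -0.019 and 0.0055; dhh1-delta had 275 XUTs and a median of -0.038. BDF1 (-0.0052) and DUS3 (-0.021) turned in the libraries labelled ski2-delta.

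With spike-in factors the features were 56, 56, 115, 66 and 1575, XUTs 14, 15, 28 and 17 in the first 4, and XUT medians -0.22, -0.39, -0.37, -0.13 and -0.69. With those factors and no first WT library the features were 12, 4, 41 and 41 in the first 4, XUTs 6, 2, 10, 8 and 225, and XUT medians 0.18, 0.012 and 0.041 in the first 3 and -0.30 in dhh1-delta. Genes that turned with spike-in factors in the libraries labelled ski2-delta were the helicase genes ECM32 (-0.28), SLH1 (-0.22), SKI2 (-0.21), DHH1 (-0.10), MSS116 (-0.023), ROK1 (-0.032), DRS1 (-0.057) and DBP7 (-0.058), the ribosome biogenesis genes NOP4 (-0.0047) and NOP58 (-0.032), and the translation factors TIF4631 (-0.070), RPG1 (-0.075), FUN12 (-0.11) and GCD1 (-0.19). So did the RNA decay and quality control genes SCD6 (-0.15), NMD2 (-0.047), NRD1 (-0.068), MTR3 (-0.11), RRP46 (-0.14), HBS1 (-0.036), RQC1 (-0.21) and RKR1 (-0.21), the stress genes HSP26 (-0.026), YDJ1 (-0.20), HSP42 (-0.18) and HSP104 (-0.21), and the iron and copper genes SIT1 (-0.065) and CCC2 (-0.14). The others were LYS20 (-0.019), LYS4 (-0.14), HIS7 (-0.15), ASN1 (-0.22), the histone gene HHO1 (-0.18), and the neighbours VPS33 (-0.26), AFG2 (-0.21), BDF1 (-0.31) and DUS3 (-0.34). In the libraries labelled dbp1-delta DHH1 (-0.052), ARN1 (-0.024) and MRP51 (-0.16) turned.

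Leaving out each replicate in turn, with the lone library assumed to vary like the other groups, gave 1 to 2, 1 to 2, 48 to 3749, 20 to 3077 and 2206 to 3112 features, 0 to 1, 0 to 1, 6 to 118, 5 to 169 and 257 to 373 XUTs, and XUT medians of -0.10 to 0.062, -0.20 to -0.041, 0.15 to 0.32, 0.22 to 0.41 and -0.60 to -0.43. Of 170 list tests camera called 88 with the preset correlation, 2 with the estimated correlation and 58 against protein-coding genes. The 2 were the snoRNAs, to which the values are scaled, in the libraries labelled ski2-delta and dbp1-delta. Against protein-coding genes the ribosomal proteins turned to lower in the libraries labelled ski2-delta (camera, adjusted p = 0.00773).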

Other observations

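Transcripts of the 2-micron plasmid fell in dhh1-delta, all 4 of them: R0010W by 2.11 on the log2 scale (standard error 0.18), R0030W by 1.97 (0.14), R0020C by 0.96 (0.11) and R0040C by 0.52 (0.13), n = 2 against 2. Relative to all features their median was -1.27 there, -0.46 in ecm32-delta, -0.23 in slh1-delta, and -0.45 and -0.21 in the libraries labelled ski2-delta and dbp1-delta (adjusted p = 0.658, 0.605, 0.658, 0.670 and 0.813 with an estimated correlation). Outside dhh1-delta 0 fell over all features as deposited. R0040C rose in the libraries labelled dbp1-delta, by 0.45 as deposited, and did not pass with protein-coding factors. With protein-coding factors 2 of 4 fell in the libraries labelled ski2-delta. Adjusted over the list alone, 3 fell in ecm32-delta and 2 in slh1-delta.

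IRC13 and MIN10 fell in the libraries labelled ski2-delta and dbp1-delta and in dhh1-delta: IRC13 by 2.46, 2.28 and 1.60, MIN10 by 0.91, 0.67 and 0.98. MIN10 passed in 2 of 4 fits without 1 library in the libraries labelled dbp1-delta (adjusted p of up to 0.0800). In ecm32-delta and slh1-delta IRC13 stood at 0.11 and -0.17 and MIN10 at 0.08 and 0.03, none past the threshold. As a hypothesis, chosen after the result was seen, the fall of IRC13 could follow a fall of the U3 snoRNA gene SNR17A, which it overlaps. SNR17A stood at 0.13 and 0.15 in the libraries labelled dbp1-delta and ski2-delta and at 0.55 in dhh1-delta, so the hypothesis is not borne out. RPL29, a neighbour of MIN10 (chromosome VI, 223258 to 223437), did not pass (0.17, 0.23 and -0.22).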
